A study of Homo sapiens with 20 samples.

How the data were processed

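The cells were HEK293-GR, a human embryonic kidney line made to express the glucocorticoid receptor (GR) constitutively. RNA was measured in 16 libraries of poly(A)-selected RNA, 4 in each of 4 groups. Cells were transfected with a pool of small interfering RNAs against the corepressor BCOR (siBCOR) or with a control pool (siNON), at 20 nM for 72 h, and then received dexamethasone, a synthetic glucocorticoid, at 100 nM for 6 h or its ethanol vehicle. BCOR binding to chromatin was measured by ChIP-seq after 1 h of hormone or vehicle, with 2 libraries for each treatment.

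The deposited table holds raw read counts over exons, which per the file headers came from HOMER without adjustment for depth, for 65572 RefSeq transcripts in the hg19 genome. The submitters' processing notes name Trimmomatic, TopHat2, FastQC and HOMER 4.10.3 for the RNA data, and Bowtie 0.12.9, HOMER and bedtools for the ChIP data. The authors give the binding sites as 3 peak lists, called vehicle-enriched, dex-enriched and shared, and how a peak was put in its class is not stated. The score column of the deposited peak lists is 0 for every peak, so peaks could not be ranked.

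Isoforms of a gene share reads, and counts summed over all transcripts came to 2.72 to 2.77 times the library total in the header. The transcript with the most reads over all libraries therefore stood for each gene symbol, which left 27896 symbols. The 134 transcripts without a gene name, which held 0.0664% of the counts, were left out. Counting did not separate strands, so overlapping genes share reads: the antisense transcript PCNA-AS1, 383 nucleotides long, had 24.3% as many reads as PCNA. Genes with too few reads were removed with edgeR's default filter, and 16432 genes were tested, of which 14346 code for protein. The deposited annotation lists 228 of them with several copies, and what these copies are was not examined. Among genes named below it does so for HSPA1B (5), PSMB9 (8), RING1 (6) and RPS18 (6), all on chromosome 6.

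Library totals in the header ran from 19377735 to 29452567 reads, and counts over the chosen transcripts from 18580294 to 28054808. Libraries were scaled by the trimmed mean of M values (TMM), and a model with 4 group means was fitted in edgeR 4.0.16 (R 4.3.3, limma 3.58.1) with quasi-likelihood F tests. The contrasts were dexamethasone against vehicle in siNON and in siBCOR cells, siBCOR against siNON in vehicle and in dexamethasone, the difference between the hormone's effects in the 2 kinds of cell (the interaction), and the average hormone effect. Every adjusted p of a gene is two-sided, from that test, with the Benjamini-Hochberg adjustment over all genes tested, and a gene was called at a false discovery rate of 0.05. Log2 fold changes used edgeR's default prior count, and a prior count of 2 went only into the log2 CPM behind the list tests and the axis of variation within groups. Levels are given as CPM, edgeR's read counts scaled to library size, as mean ± SD with n = 4 per group, and log2 fold changes are given ± SE. Where a group had 0 counts, the fold is a lower bound against 3 counts over the whole group. Confidence intervals are at 95%, and they and the floors cover counting error only.

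The comparisons, the tests, the thresholds, the naming rule and 21 gene lists were chosen before the data were examined. The rule names BCOR and the receptor gene NR3C1. In each comparison it names the 10 called genes with the largest change in each direction, with a mean of at least 50 counts and no overlap between the libraries of the compared groups (overlap was not looked at for the interaction). It also names up to 4 called members of each list with the smallest adjusted p. Peaks are named if they lie within 50 kb of the transcription start site (TSS) of such a gene. Any other gene is given as chosen after its values were seen.

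The lists hold glucocorticoid-induced, NF-kB and inflammatory, immediate early, PRC1.1 complex, PRC2 complex, Polycomb-type developmental, GR and coregulator, G1/S, G2/M, growth control, adhesion and migration, interferon-stimulated, stress response (unfolded protein and integrated), p53 target, cholesterol synthesis, neuronal, immune cell, fibroblast, epithelial, ribosomal protein and housekeeping genes. Each was tested with camera in limma, which asks whether a list's genes rank higher or lower than the other genes, at a preset correlation between genes of 0.01, adjusted over the 21 lists of a comparison. Camera was repeated with a correlation estimated from the data, and fry was run on the same lists. The fry p tests whether a list's genes move, on balance, one way, its mixed p whether they change in either direction, and neither compares a list with other genes.

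The size of the hormone response after BCOR depletion was the slope, by total least squares across genes, of the log2 fold changes in siBCOR cells on those in siNON cells. It was first computed with an intercept, and the line was made to pass through the origin only after those values had been seen. Its error is a jackknife over libraries. Genes near peaks were compared with other tested genes by Fisher's exact test, two-sided, adjusted over 9 such tests, of which 3 were added after the data were seen. Under alternatives these tests were not adjusted and were called at an unadjusted p under 0.05.

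Alternatives to the processing were other scalings (relative log expression, upper quartile, DESeq2 1.42.0), no filter or a mean of at least 50 counts, voom, the DESeq2 Wald test, and a log2 fold change of at least 0.5. Further ones were a replicate block, fits of only the compared groups, each library left out in turn, windows of 10 and 100 kb, the nearest TSS, and genes matched on expression. Alternatives chosen after seeing the data were a covariate for the main axis of variation within groups, with library positions centred by group (within-group axis) or not (axis score), 2 libraries left out together, the longest transcript of each gene, a 1 kb window and a subset of peaks by name. Recovery was tested on simulated data for dexamethasone in siNON cells, for depletion in vehicle and for the interaction, with 100 genes changed by 1.5-fold and 100 by 2-fold. The fit recovered, in that order, 78%, 78% and 44% of the smaller changes and 97%, 98% and 92% of the larger ones. The changed genes were drawn only from those with an expected count of at least 50. Counts of different genes were drawn independently, without the axis of variation that the real libraries share. Recovery in the real data may therefore differ from these rates.

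No hg19 genome sequence or exon annotation was used here, so GC content, motifs and exon positions were not analysed, and raw reads and ChIP signal were not used here. Gene positions are those of the count table. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.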

Results

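RNA was measured in HEK293-GR cells in 4 groups of 4 replicates each: siNON vehicle, siNON dex, siBCOR vehicle and siBCOR dex. Counts over the chosen transcripts came to 25461027, 20658272, 24009426 and 22411464 in siNON vehicle replicates 1 to 4, and to 22654922, 23675949, 23577542 and 18580294 in siNON dex. They were 25596855, 20125940, 19964802 and 21143745 in siBCOR vehicle, and 25811314, 28054808, 21421310 and 19034784 in siBCOR dex. The series text names 3 replicates for the expression data, while 4 are labelled and all 4 were used. BCOR chromatin binding was given as 267 vehicle-enriched, 3055 dex-enriched and 8587 shared peaks, from 2 libraries for each treatment.

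BCOR, the depleted gene (transcript NM_001123385, hg19 chromosome X, 39910499 to 39956719), stood at 226.8, 210.3, 158.8 and 188.6 CPM in siNON vehicle replicates 1 to 4, and at 96.76, 102.1, 105.9 and 70.64 CPM in siNON dex. It stood at 23.51, 22.28, 21.81 and 21.85 CPM in siBCOR vehicle, and at 15.46, 14.82, 14.93 and 13.77 CPM in siBCOR dex. Depletion lowered BCOR 8.77-fold in vehicle (log2 fold change -3.13 ± 0.123, adjusted p = 1.24e-10) and 6.36-fold in dexamethasone (-2.67 ± 0.123, adjusted p = 1.49e-09). Dexamethasone itself lowered BCOR in siNON cells (-1.06 ± 0.113, adjusted p = 1.51e-06) and in siBCOR cells (-0.60 ± 0.122, adjusted p = 0.00157), and these responses did not differ past the threshold (0.46, adjusted p = 0.221). The receptor gene NR3C1 (NM_001204258, chromosome 5, 142657496 to 142783254) fell with hormone from 997.8 ± 65.3 to 706.2 ± 29.7 CPM in siNON cells (-0.50 ± 0.0533, adjusted p = 1.53e-06), and in siBCOR cells too (-0.36 ± 0.0532, adjusted p = 7.74e-05). After depletion NR3C1 was higher in dexamethasone (0.29, adjusted p = 0.000796) and not called in vehicle (0.15, adjusted p = 0.0616). Reads of the endogenous NR3C1 gene were not told apart from any reads of the receptor that this line was made to express. The NR3C1 changes therefore cannot be assigned to the endogenous gene.

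**Figure D1:**
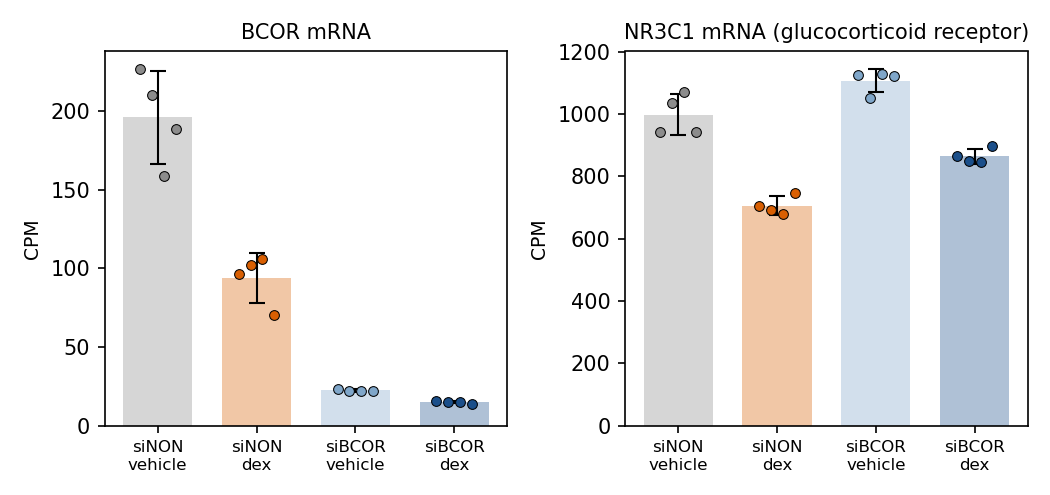
BCOR and NR3C1 levels (CPM, read counts scaled to library size) in the 4 groups. Bars are means, error bars are SD and points are the 4 libraries. BCOR lies at 23.51 CPM or lower in every siBCOR library and at 70.64 CPM or higher in every siNON library.

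The first comparison asked which genes the hormone changes in cells with BCOR. Dexamethasone raised FKBP5, a cochaperone of GR (chromosome 6, 35541362 to 35656692), from 103.2 ± 1.81 to 517.9 ± 12.9 CPM, a 5.02-fold rise. It raised the kinase gene SGK1 (chromosome 6, 134490384 to 134496034) 20.4-fold (4.35 ± 0.105), PDK4, which limits glucose oxidation (chromosome 7, 95212809 to 95225925), 40.3-fold (5.33 ± 0.118), and CDKN1C, an inhibitor of cyclin-dependent kinases (chromosome 11, 2904448 to 2906995), 38.9-fold (5.28 ± 0.147). The calcium-binding gene S100P (chromosome 4, 6695566 to 6698897) went from 0.521 ± 0.214 to 114.4 ± 12.2 CPM (7.78 ± 0.152). SLC6A19, an amino acid transporter (chromosome 5, 1201710 to 1225230), had 0 counts in all vehicle libraries and 12.4 ± 1.56 CPM in siNON dex, which is at least 378-fold higher. The growth regulator MYC (chromosome 8, 128747680 to 128755197) fell from 214.2 ± 24.2 to 33.1 ± 3.01 CPM (-2.69 ± 0.1, adjusted p = 1.11e-12 by edgeR). ADAMTS1, a matrix protease (chromosome 21, 28208606 to 28217728), fell 9.11-fold (-3.19 ± 0.0712, adjusted p = 2.82e-15 by edgeR, n = 4 in each group).

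Every gene named for the size of its change, here and in the comparisons that follow, except for the interaction, moved the same way in all libraries, since the compared groups did not overlap. The other genes with the largest rise in siNON cells were SLC6A3 (8.33), LOC100506585 (7.84, which shares reads with PTPRN2), the tubulin genes TUBA3E (7.69) and TUBA3D (5.72), LOC285097 (6.83), RASD1 (6.13), a small GTPase, and PGC (5.45). SLC6A3, LOC100506585, TUBA3E, LOC285097 and PGC had only 7, 5, 7, 11 and 10 counts over the siNON vehicle group, so their folds are imprecise. The other large falls were in ZNF711 (-3.28 ± 0.214), the helix-loop-helix gene ID4 (-2.61), ARRDC4 (-2.40), CDH7 (-2.34), the Notch target HES1 (-2.12), ANOS1 (-2.11), PCDH19 (-2.08) and MID1 (-2.05). Among the 38 glucocorticoid-induced genes 28 rose, with FKBP5, SGK1, PDK4 and NFKBIA (2.79 ± 0.0696) the most certain, 0 fell and 10 were not called; adjusted over the list alone 31 rose and 1 fell (camera adjusted p = 4.05e-34). Of 98 Polycomb-type developmental genes, 5 rose, 57 fell and 36 were not called, and adjusted over the list alone 6 rose and 65 fell (camera adjusted p = 2.29e-23, and adjusted p = 0.0754 with an estimated correlation). HOXA9 (-1.99), HOXA10 (-1.58), FOXC1 (-1.42) and HOXC4 (-1.38), which pattern the body axis or organs, fell, where reads of the HOXA9 and HOXA10 region are shared. Immediate early genes (4 rose, 12 fell, 12 not called; 4 and 13 adjusted over the list alone) ranked lower (camera adjusted p = 0.0156, and adjusted p = 0.65 with an estimated correlation), with JUN at -1.2, DUSP5 at -1.33 and PHLDA1 at 3.23. Adhesion and migration genes (8 rose, 21 fell, 34 not called; 10 and 22 adjusted over the list alone) ranked lower too (camera adjusted p = 0.0156, and adjusted p = 0.65 with an estimated correlation), with NRP1 at -1.29 and RHOB, a GTPase of the cytoskeleton, at 1.86. The p53 targets (10 rose, 2 fell, 13 not called; the same 10 and 2 adjusted over the list alone) ranked higher (camera adjusted p = 0.0228, and adjusted p = 0.0754 with an estimated correlation), with BTG2 at 0.83 and SESN1 at 0.73.

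Among lists that camera did not call in siNON cells, growth control genes gave 5 higher, 11 lower and 20 not called (6 and 12 adjusted over the list alone; camera adjusted p = 0.0675), with CDKN1A at 2.33 and IGFBP5 at -1.73. NF-kB and inflammatory genes gave 3, 1 and 15 (PLAUR 2.07, TNFAIP3 1.12, BCL3 -0.74), and cholesterol genes 4, 6 and 14 (NSDHL 1.33, HMGCS1 -1.37). Stress response genes gave 4, 5 and 19 (ATF3 -1.14, HERPUD1 0.79), and interferon-stimulated genes 6, 1 and 21 (IFIT3 1.32, IFI44L -1.48). G1/S genes gave 6, 1 and 35 (SLBP 0.49), and G2/M genes 5, 1 and 48 (TACC3 0.74, CKS2 -0.39). GR and coregulator genes gave 2, 5 and 20 (NR3C2 -0.96), neuronal genes 1, 3 and 20 (ELAVL2 -0.85), and epithelial genes 2, 4 and 5 (KRT8 0.53, KRT19 -0.92). PRC1.1 genes gave 1, 1 and 9, PRC2 genes 2, 1 and 8 (PHF19 0.54, JARID2 -0.28), fibroblast genes 2, 0 and 7 (COL6A1 0.67), and housekeeping genes 2, 0 and 12 (POLR2A 0.52). None of the 48 ribosomal protein genes or 8 immune cell genes was called. Median, mean and test direction differed in sign for NF-kB (-0.0453, 0.0756, higher), PRC2 (-0.0209, 0.0149, higher), growth control (-0.121, 0.00256, lower) and stress response genes (0.0456, -0.0802, lower), and the median of G1/S genes changed sign under another scaling.

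In all, 1748 genes rose and 1411 fell with dexamethasone in siNON cells by edgeR's quasi-likelihood test, of which 394 rose and 226 fell at least 2-fold. The share that rose was 55.3%, and 47.4% without a filter, 49.6% without siNON vehicle replicate 3 and 46.8% with the within-group axis as a covariate. The libraries of both treatments did not overlap in 3262 of the 16432 genes, where chance gives 2.86%. With an estimated correlation between genes, camera's call held for the glucocorticoid-induced list in siNON and in siBCOR cells (adjusted p = 4.93e-06 and 1.07e-05) and for no other list in any comparison. Without siNON dex replicate 4, which stands apart from the other replicates of its group, 28 glucocorticoid-induced genes rose and 0 fell, 5 and 56 Polycomb-type genes did, and camera no longer called the immediate early (adjusted p = 0.115), adhesion (0.142) and p53 (0.12) lists.

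The same question in cells depleted of BCOR gave 1715 genes that rose and 2062 that fell, 406 and 181 of them at least 2-fold. More rose than fell without siNON dex replicate 4 and siNON vehicle replicate 3 (3096 and 2538), in a fit of only the 2 groups (2379 and 2298), with the within-group axis (4085 and 3340) and for a log2 change of at least 0.5 (1046 and 805). FKBP5 rose 4.58-fold (2.2 ± 0.0556), SGK1 19.2-fold (4.26 ± 0.105), PDK4 57.7-fold (5.85 ± 0.12) and S100P 83.5-fold, from 0.767 ± 0.112 to 64.2 ± 2.95 CPM (6.38 ± 0.144). TIPARP, an ADP-ribosyltransferase that shares reads with its antisense transcript (chromosome 3, 156392205 to 156424557), rose 32-fold (5.00 ± 0.123) from 36.7 ± 5.22 CPM. SLC6A19 went from 0 counts to 4.96 CPM, at least 146-fold higher. MYC fell (-2.61), as did ADAMTS1 (-3.17 ± 0.0708, adjusted p = 3.42e-15 by edgeR, n = 4).

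The other large rises in siBCOR cells were in SLC6A3 (6.90 ± 0.235), LOC285097 (6.35), RASD1 (6.12) and LOC285847 (5.59). SLC6A3 and LOC285097 had only 8 and 7 counts over the siBCOR vehicle group, so their folds are imprecise. TUBA3E and LOC100506585, with 1 and 3 counts over the siBCOR vehicle group, rose too, and no fold is given for them. The other large falls were in ZNF711 (-2.47), ID4 (-2.35), the developmental factor SOX4 (-2.21 ± 0.0548), GPRC5A (-2.21), RNF122 (-2.2), RGS16 (-2.18), the chaperone HSPA1B (-2.15, annotated with 5 copies) and HOXA10-HOXA9 (-2.02). Glucocorticoid-induced genes again rose, with 29 higher, 1 lower and 8 not called, and 30 and 1 adjusted over the list alone (camera adjusted p = 1.17e-29). Polycomb-type genes gave 5 higher, 57 lower and 36 not called, and 5 and 60 adjusted over the list alone (camera adjusted p = 3.5e-19, and adjusted p = 0.13 with an estimated correlation), with HOXA9 at -1.94 and POU3F2 at -1.46. Adhesion genes gave 10, 31 and 22, and 14 and 35 adjusted over the list alone (camera adjusted p = 0.00172, and 0.386 with an estimated correlation), with RHOB at 1.65, RHOU at 1.77 and the neuropilins NRP1 and NRP2 at -1.42 and -1.39. Growth control genes gave 6, 15 and 15, and 6 and 16 adjusted over the list alone (camera adjusted p = 0.0252, and 0.386 with an estimated correlation), with CDKN1A at 2.68, CDKN1C at 4.57 and IGFBP5 at -1.96. Cholesterol genes gave 2, 7 and 15, and 4 and 10 adjusted over the list alone (camera adjusted p = 0.0339, and 0.172 with an estimated correlation), with INSIG1 at -1.11 and HMGCS1 at -1.09. GR and coregulator genes gave 1, 7 and 19, and 1 and 10 adjusted over the list alone (camera adjusted p = 0.0339, and 0.335 with an estimated correlation), with NR3C2 at -1.08 and TBL1X at -0.55. The p53 targets ranked higher, with 5 that rose, 1 that fell and 19 not called, and 5 and 1 adjusted over the list alone (camera adjusted p = 0.0252, and 0.0905 with an estimated correlation). Immediate early genes were not called as a list (5 rose, 10 fell, 13 not called; 6 and 12 adjusted over the list alone; camera adjusted p = 0.0944).

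With siNON dex replicate 4 and siNON vehicle replicate 3 both left out of the joint fit, 10 p53 targets rose and 2 fell. Median, mean and test direction differed in sign for interferon-stimulated (-0.00425, 0.0153, higher) and neuronal genes (0.0327, -0.0574, lower), and the medians of neuronal and PRC1.1 genes changed sign under upper-quartile scaling. The libraries of both treatments did not overlap in 5046 genes, where chance gives 2.86%.

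Of the genes that rose in siNON cells, 980 (56.1%) also rose in siBCOR cells, where independent lists would share 182.4, and 922 (65.3%) of those that fell also fell, where they would share 177.1. No gene rose in siNON and fell in siBCOR cells, and 2 went the opposite way. Across genes, which are not independent replicates, the responses correlated with r = 0.801. The slope of the siBCOR on the siNON response was 0.949 (jackknife SE 0.0391) over the 2171 genes higher in the average hormone effect and 0.992 (SE 0.0903) over the 2391 lower ones, so neither differed from 1 by 2 SE. With an intercept, the form computed first, the slopes were 0.936 and 0.847. The median ratio of the responses was 0.892 for the higher and 1.19 for the lower genes. It was 0.668 and 0.808 over genes called in siNON cells, and 1.05 and 1.36 over genes called in siBCOR cells. Its side of 1 thus depended on how genes were chosen. For the lower genes the slope depended on how they were chosen, at 0.871 over genes called in siNON cells and 1.11 over genes called in siBCOR cells.

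**Figure D2:**
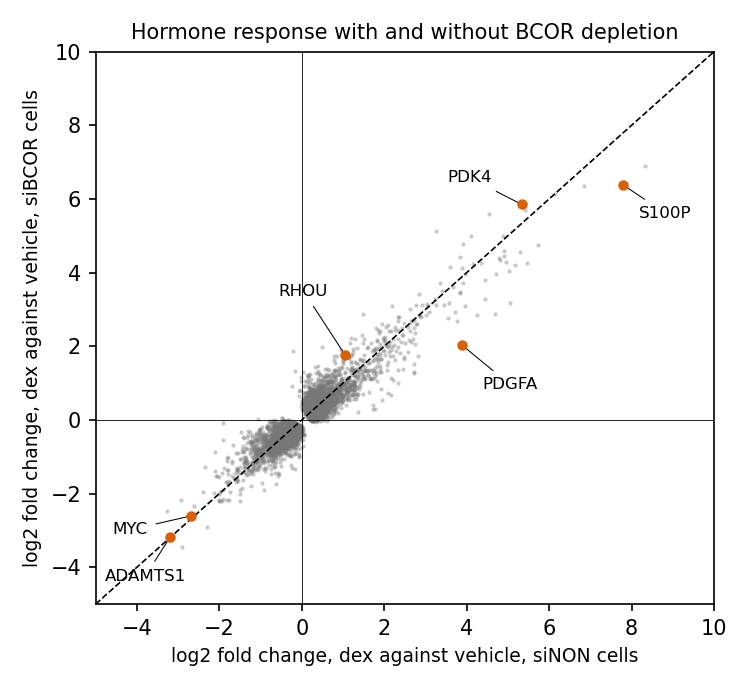
Log2 fold change with dexamethasone in siBCOR cells (vertical) against siNON cells (horizontal) for 4539 genes called in the average hormone effect, each point a gene, with 23 genes left out because a group held at most 3 counts. The dashed line marks equal responses. PDGFA and S100P lie below the line and RHOU above it.

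The interaction asked which genes respond differently to dexamethasone when BCOR is depleted, the question in the series title, which concerns genes of cell growth and mobility. PDGFA, a growth factor (NM_002607, chromosome 7, 536897 to 559481), rose 14.8-fold in siNON cells, from 2.94 ± 0.399 to 43.6 ± 3.45 CPM, but 4.07-fold in siBCOR cells, from 2.46 ± 0.427 to 10.1 ± 0.743 CPM (interaction -1.86 ± 0.171, adjusted p = 7.27e-05 by edgeR, n = 4 per group). Of the 13 interaction genes within the naming rule, PDGFA and ACSL1 were called under all 27 alternatives and NSDHL under 25. RHOU was called under 15, ELK1 under 12, APOLD1, FJX1 and SNX33 under 10, INSIG1 under 9, GLUL under 8, and S100P, SHC1 and SLC39A14 under 7. These counts include alternatives chosen after the data were seen, which called all 13 genes each time (52 of 52 values). One of them, the within-group axis, adds calls by construction. Under alternatives chosen beforehand 122 of 299 values were called. The responses of S100P (-1.40 ± 0.257, adjusted p = 0.0457), APOLD1, a gene of the vessel lining (-0.98 ± 0.169), and the transcription factor gene ELK1 (-0.72 ± 0.119) were smaller in siBCOR cells. So were those of the sterol enzyme gene NSDHL (-0.69 ± 0.0993, adjusted p = 0.0143) and the acyl-CoA ligase gene ACSL1 (-0.63 ± 0.0838, adjusted p = 0.00781). ACSL1, for example, went from 63.5 to 303.7 CPM in siNON cells and from 76.6 to 237.2 CPM in siBCOR cells. RHOU, a GTPase of cell shape and movement (chromosome 1, 228870824 to 228882416), rose more in siBCOR cells, from 36.2 ± 3.78 to 123.8 ± 5.68 CPM, than in siNON cells, from 47.0 ± 4.45 to 96.8 ± 8.04 CPM (0.73 ± 0.119, adjusted p = 0.0344). FJX1 fell in siNON cells from 26.4 ± 2.41 to 15.1 ± 2.16 CPM and was not called in siBCOR cells, where it stood at 28.5 and 27.8 CPM (0.77 ± 0.133, adjusted p = 0.035).

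**Figure D3:**
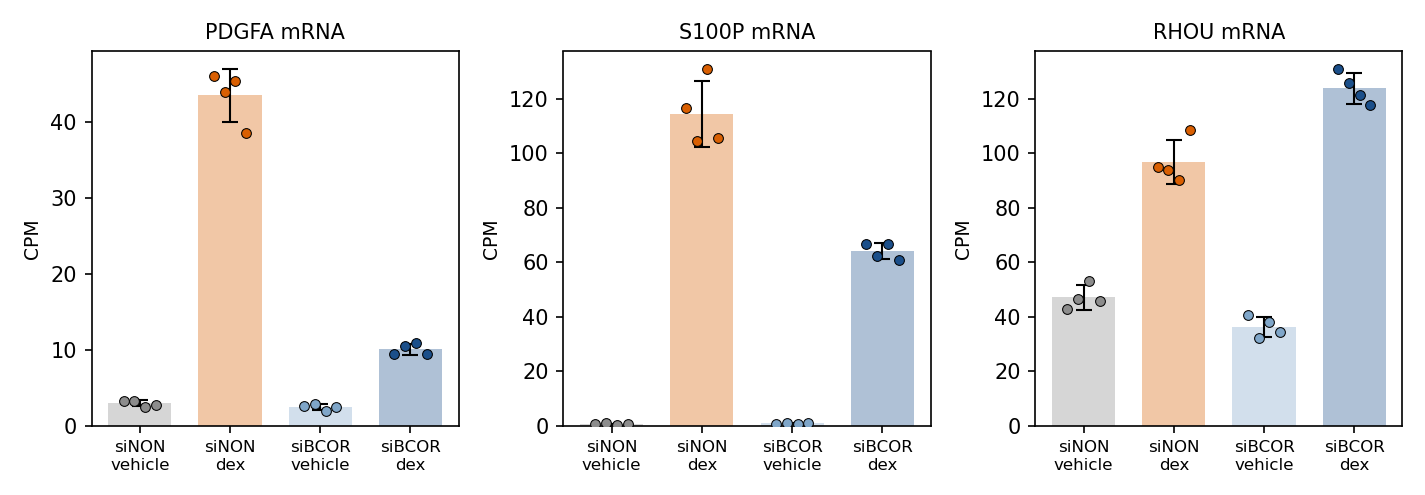
PDGFA, S100P and RHOU levels (CPM, read counts scaled to library size) in the 4 groups, with bars for means, error bars for SD and points for the 4 libraries. With dexamethasone PDGFA reaches 43.6 CPM in siNON and 10.1 CPM in siBCOR cells, and RHOU reaches 96.8 and 123.8 CPM.

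In all, 17 genes had an interaction, 14 below and 3 above 0, while 3129 had an unadjusted p under 0.05. The others below 0 within the naming rule were SNX33 (-0.63 ± 0.102), SLC39A14 (-0.48), a zinc transporter, GLUL (-0.47), SHC1 (-0.44) and INSIG1 (-0.39). SNORD137 (-2.15), RTL9 (-1.43) and TUBA3FP (-1.43) below 0 and SOX18 (1.17) above it were chosen after their values were seen, and their group means are 3.83 CPM or lower, from 0.226 CPM in SNORD137 to 3.83 CPM in TUBA3FP. Cholesterol genes gave 0 above, 2 below (NSDHL and INSIG1) and 22 not called, and 0 and 7 adjusted over the list alone (camera adjusted p = 0.0233, and adjusted p = 0.21 with an estimated correlation). Of the glucocorticoid-induced genes 1, GLUL, was called below 0 (1 above and 5 below adjusted over the list alone), and of the adhesion genes 1, RHOU, above it (1 and 1). Immediate early genes had 1 above and p53 targets 1 above and 1 below adjusted over the list alone, and no other list had a called member. Median, mean and test direction differed in sign for glucocorticoid-induced (0.0144, -0.0331, lower), PRC1.1 (-0.0473, 0.06, higher), fibroblast (-0.0941, 0.011, higher) and epithelial genes (0.059, -0.00324, lower), and the medians of glucocorticoid-induced and Polycomb-type genes changed sign under upper-quartile scaling.

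The interaction count rested on which libraries were used. Without siNON dex replicate 4 it was 2429, of which 1354 lay above and 1075 below 0, so the balance of directions turned. All 17 genes were among the 2429, and without any other library the count was 2 to 7. It was 6, 6, 6 and 5 in turn without siNON vehicle replicates 1 to 4, and 4, 4 and 2 without siNON dex replicates 1 to 3. It was 7, 6, 7 and 3 without siBCOR vehicle replicates 1 to 4, and 2, 3, 3 and 3 without siBCOR dex replicates 1 to 4. Without siNON dex replicate 4 the cholesterol list gave 1 above and 7 below 0 and camera no longer called it (adjusted p = 0.232). Within groups, libraries varied along a main axis that held 59.9% of the within-group variance of 13430 genes, on which siNON dex replicate 4 and siNON vehicle replicate 3 lay at -27.5 and -27.0 and siBCOR vehicle replicate 2 at 23.9, as distances from their group's mean. With these distances (the within-group axis) as a covariate the count was 4872, all 17 genes included. With the axis score, the position on the same axis without centring by group, it was 96, of which 16 were among the 17. The within-group axis was drawn from the spread of these same libraries, so as a covariate it shrinks that spread and adds calls by construction.

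**Figure D4:**
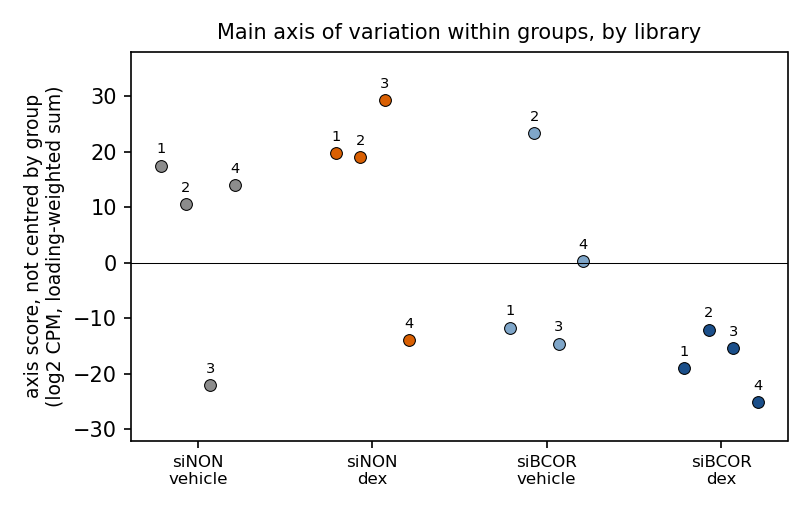
Axis score of each library (vertical, arbitrary units), which is its position on the main axis of variation within groups before centring by group, by group (horizontal), with replicate numbers as labels. The siNON vehicle 3 and siNON dex 4 libraries lie at -22.0 and -13.9, apart from the other 6 siNON libraries at 10.5 to 29.3.

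Depletion of BCOR in vehicle asked which genes BCOR holds up or down without hormone. SOCS2, an inhibitor of cytokine signalling that shares reads with its antisense transcript (chromosome 12, 93964757 to 93970521), rose from 6.87 ± 0.93 to 18.7 ± 1.09 CPM (1.45 ± 0.0916, adjusted p = 7.9e-08 by edgeR, n = 4). The mitochondrial gene CHCHD10 (chromosome 22, 24108021 to 24110159) fell from 60.6 ± 11.5 to 16 ± 2.4 CPM (-1.92 ± 0.136, adjusted p = 2.19e-07). CLSTN2, a synaptic cadherin (chromosome 3, 139654027 to 140286919), fell from 8.0 ± 1.23 to 2.38 ± 0.235 CPM (-1.74 ± 0.114, adjusted p = 1.03e-07). FGFR3, a receptor for fibroblast growth factors (chromosome 4, 1795039 to 1810599), fell from 33.4 ± 2.24 to 13.9 ± 2.23 CPM (-1.26 ± 0.107), and its relative FGFR1 fell too (-0.72 ± 0.065). The glucocorticoid target TSC22D3 fell from 379.1 to 205.0 CPM (-0.89 ± 0.116), whereas KLF9 rose (0.72 ± 0.102).

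The other genes that rose most after depletion in vehicle were the paired LOC102724593 (1.12) and LOC101927699 (1.07), and STON1-GTF2A1L (1.04) and STON1 (0.94), which share reads. The liver enzyme genes MAT1A (1.00 ± 0.101) and CPS1 (0.99 ± 0.113), PSMB9 (0.98), the kinase gene BTK (0.94) and the neuronal gene MAP2 (0.93) rose too. The other large falls were in the receptor gene GRIK3 (-1.88 ± 0.183), PCGF5, a Polycomb ring finger gene (-1.83 ± 0.244), PLPPR2 (-1.67), NTS (-1.57), PLXNA4 (-1.36), MROH6 (-1.34) and TPRN (-1.30). Of 48 ribosomal protein genes 0 rose, 26 fell and 22 were not called, and 0 and 32 did adjusted over the list alone (camera adjusted p = 4.13e-16, and adjusted p = 0.392 with an estimated correlation), with RPS12 at -0.47, RPS18 at -0.52 and RPL18 at -0.51. G1/S genes gave 3, 12 and 27, and 3 and 12 adjusted over the list alone (camera adjusted p = 0.00194, and 0.392 with an estimated correlation; UHRF1 -0.50, RRM2 -0.35). Immediate early genes gave 1, 7 and 20, and 1 and 7 adjusted over the list alone (camera adjusted p = 0.00335, and 0.485 with an estimated correlation; JUNB -0.94, JUN -0.50, NR4A2 0.67). Stress response genes gave 0, 5 and 23, and 1 and 6 adjusted over the list alone (camera adjusted p = 0.0036, and 0.392 with an estimated correlation; CRELD2 -0.44). Growth control genes gave 2, 8 and 26, and 4 and 12 adjusted over the list alone (camera adjusted p = 0.0164, and 0.392 with an estimated correlation; IGF2 -1.15, which shares reads with INS-IGF2). Neuronal genes gave 3, 8 and 13, and 4 and 9 adjusted over the list alone (camera adjusted p = 0.0251, and 0.24 with an estimated correlation; TUBB3 -0.92, SYP -0.81). Epithelial genes gave 0, 4 and 7, and 0 and 4 adjusted over the list alone (camera adjusted p = 0.0492, and 0.392 with an estimated correlation; CDH1 -0.56, EPCAM -0.24).

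Among lists not called in vehicle, glucocorticoid-induced genes gave 5 higher, 3 lower and 30 not called, and Polycomb-type genes 15, 12 and 71 (FOXC1 -0.67, HOXA11 0.41), of which 10 were higher and 21 lower (median -0.0526) without siNON dex replicate 4 and siNON vehicle replicate 3. G2/M genes gave 9, 1 and 44 (KIF2C 0.32), and adhesion genes 2, 8 and 53 (PLXNA2 -0.94, VIM -0.42). Interferon-stimulated genes gave 4, 0 and 24 (IFIT2 1.00), cholesterol genes 3, 4 and 17 (DHCR7 -0.52, HSD17B7 0.64), and PRC1.1 genes 1, 2 and 8 (RING1 -0.53, and BCOR). The medians of Polycomb-type and G2/M genes changed sign under relative log expression and DESeq2 scaling, and those of p53 and interferon-stimulated genes under all 3 other scalings, while that of ribosomal genes kept its sign. Median, mean and test direction differed in sign for PRC1.1 (0.0615, -0.256, lower), PRC2 (-0.0134, 0.0165, higher), Polycomb-type (0.0301, -0.0142, higher), p53 (0.0145, -0.0282, lower) and housekeeping genes (0.04, -0.0133, lower).

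In all, 1450 genes rose and 1345 fell after depletion in vehicle, 48 and 96 of them at least 2-fold, and libraries did not overlap in 2964 genes, where chance gives 2.86%. The share that rose was 51.9% with TMM, 40.6% with relative log expression, 42.9% with upper-quartile and 41.2% with DESeq2 scaling, and 41.6% without a filter. It was 34.4% (1053 rose and 2011 fell) without siNON vehicle replicate 3 and 37.7% (1509 and 2490) without siNON dex replicate 4 as well. Without siBCOR vehicle replicate 1 the count was 1803. With siNON vehicle replicate 3 and siNON dex replicate 4 both left out, 14 growth control, 11 stress response and 11 immediate early genes fell, and with the axis score as a covariate 20 G1/S and 12 stress response genes did.

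In dexamethasone, the comparison of depleted with control cells asked the same with the hormone present. PDGFA was lower (-2.12 ± 0.102, adjusted p = 1.49e-09), as were CLSTN2 (-2.06 ± 0.114), CHCHD10 (-1.99) and FGFR3 (-1.38), by edgeR with n = 4. CDKN1C stood at 31.5 ± 3.69 CPM against 76.3 ± 5.24 CPM in siNON cells (-1.27 ± 0.113), and the adhesion gene CDH1 (chromosome 16, 68771193 to 68869445) at 14.9 ± 1.86 against 30.8 ± 4.95 CPM (-1.04 ± 0.121). SOCS2 was higher, at 32.8 ± 1.36 against 10.5 ± 0.643 CPM (1.64 ± 0.0881, adjusted p = 5.9e-09), as were the growth factor gene FGF2 (1.21), which shares reads with NUDT6, and the integrin gene ITGB8 (1.15).

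The other large rises were in GPR137C (1.45), PGM2L1 (1.38), BTK (1.28), CREBRF (1.25), STON1-GTF2A1L (1.21), NEK10 (1.13) and BBS12 (1.12), and the other large falls in PLPPR2 (-1.94), INHBE (-1.58), B4GALNT1 (-1.53), GPER1 (-1.52), UNC5A (-1.45) and INS-IGF2 (-1.45). Ribosomal protein genes gave 0 higher, 39 lower and 9 not called, and 0 and 42 adjusted over the list alone (camera adjusted p = 5.15e-14, and 0.604 with an estimated correlation; RPL18 -0.66, RPS19 -0.55). Stress response genes gave 4, 15 and 9, and 4 and 16 adjusted over the list alone (camera adjusted p = 0.00276, and 0.473 with an estimated correlation; CRELD2 -0.56, XBP1 -0.30). Growth control genes gave 6, 16 and 14, and 6 and 16 adjusted over the list alone (camera adjusted p = 0.0299, and 0.604 with an estimated correlation). Among lists that camera did not call, glucocorticoid-induced genes gave 8 higher, 7 lower and 23 not called (KLF9 0.74, PDK4 0.59), and Polycomb-type genes 19, 12 and 67 (HOXA13 0.58). Cell cycle genes gave 6, 14 and 22 for G1/S (RRM2 -0.62, MCM5 -0.50) and 12, 8 and 34 for G2/M (KIF23 0.64, CDC20 -0.47). With the axis score as a covariate 0 G1/S genes were higher and 19 lower (median -0.154), and 6 and 7 G2/M genes (median -0.0375). Adhesion genes gave 8, 19 and 36 (NCAM1 -0.66), and cholesterol genes 4, 9 and 11 (DHCR7 -0.81 ± 0.0684). Neuronal genes gave 5, 11 and 8 (SNAP25 0.67), and GR and coregulator genes 5, 11 and 11 (CARM1 -0.67, HDAC1 -0.44). Interferon-stimulated genes gave 7, 7 and 14 (OASL -1.26), p53 targets 6, 8 and 11 (TP53INP1 0.57), epithelial genes 1, 4 and 6 (KRT8 -0.41) and housekeeping genes 2, 6 and 6 (GAPDH -0.50).

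In all, 3357 genes were higher and 3080 lower in depleted cells with dexamethasone, 123 and 154 of them at least 2-fold, and libraries did not overlap in 5618 genes, where chance gives 2.86%. The share that was higher was 52.2% with TMM, 49.7% with relative log expression, 49.0% with DESeq2 and 43.0% with upper-quartile scaling, 48.9% without a filter and 53.5% with a mean of at least 50 counts. It was 54.7% without siNON dex replicate 4, 55.4% with the within-group axis and 44.1% with the axis score as a covariate. Without siNON dex replicate 3 the count of 6437 was 4168, and with the axis score as a covariate it was 3047, of which 2262 were among the 6437; 9 stress response and 9 growth control genes then fell. The genes moved by depletion overlapped between treatments: 706 (48.7%) of those higher in vehicle were higher in dexamethasone, where independent lists would share 296.2, and 1056 (78.5%) of the lower ones were lower, where they would share 252.1. Only 8 and 3 genes went opposite ways, and r across genes, which are not independent replicates, was 0.555. Median, mean and test direction differed in sign for PRC1.1 (0.0716, -0.196, lower), G1/S (0.0124, -0.0117, lower), p53 (0.053, 0.0208, lower) and immune cell genes (0.143, 0.0683, lower). The medians of G1/S, NF-kB and p53 genes also changed sign under another scaling.

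The peaks asked where BCOR binds with and without hormone. Of the dex-enriched peaks 6.97% (interval 6.09 to 7.93) lay within 1 kb of a TSS, against 35.7% (34.7 to 36.7) of the shared and 48.7% (42.6 to 54.9) of the vehicle-enriched peaks, by exact binomial intervals. The odds ratio of dex-enriched against shared peaks was 0.135 (0.116 to 0.157; adjusted p = 5.31e-241) and that of vehicle-enriched against shared peaks 1.71 (1.33 to 2.2; adjusted p = 1.81e-05), by Fisher's exact test, two-sided, adjusted over 3 tests. The median distance to a TSS was 29390 bp for dex-enriched, 6788 bp for shared and 1161 bp for vehicle-enriched peaks. FKBP5 had dex-enriched peaks at chromosome 6, 35630974 to 35631308, 35655499 to 35655833 and 35683121 to 35683455. PDK4 had 3, the nearest at chromosome 7, 95226381 to 95226715, which is 623 bp from its TSS. S100P had a dex-enriched peak at chromosome 4, 6695088 to 6695422 (311 bp) and TIPARP at chromosome 3, 156391851 to 156392185 (187 bp). SGK1 had a shared peak at chromosome 6, 134496464 to 134496782, and SOCS2 a shared peak at chromosome 12, 93964538 to 93964882, 47 bp from its TSS.

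Genes with a peak within 50 kb were then compared with the other tested genes. Neighbouring genes can share a peak, as FKBP5 and LOC285847 did, so genes are not independent. The p-values and intervals of these tests take no account of this and can overstate certainty. Of the 2216 genes with a dex-enriched peak, 558 (25.2%) rose with dexamethasone in siNON cells, against 1190 of 14216 (8.37%) without (odds ratio 3.68, 3.28 to 4.13, adjusted p = 5.14e-100 by Fisher's exact test, two-sided, adjusted over 9 tests). Genes near shared peaks differed less (11.6% against 9.77%, odds ratio 1.21, 1.09 to 1.34, adjusted p = 0.000319), and among genes with a shared but no dex-enriched peak 8.74% rose, against 8.05% of genes with neither. Against genes matched on expression the ratio for shared peaks was 1.14 (0.996 to 1.3) and no longer called. Genes that fell with hormone were not called near dex-enriched peaks (7.76% against 8.72%, odds ratio 0.881, 0.742 to 1.04, adjusted p = 0.183), and the ratio was 1.68 when each peak was given to its nearest TSS. It was 0.871 within 100 kb, 0.844 without siNON dex replicate 4 and siNON vehicle replicate 3, and 0.773 with the axis score. Each of these lay below 1 at an unadjusted p under 0.05 by the same test. Near shared peaks such genes were more frequent (1.31, 1.17 to 1.46, adjusted p = 5.49e-06), in a test added after the data were seen. Of the 17 interaction genes 7 had a dex-enriched peak (odds ratio 4.5, 1.45 to 13.1, adjusted p = 0.0068): S100P, ELK1, SNX33, ACSL1 and SLC39A14, with RTL9 and TUBA3FP, which were chosen after their values were seen. Without siNON dex replicate 4 and siNON vehicle replicate 3 that ratio was 1.1. Its background was all tested genes. Of the genes that rose by a log2 change of at least 0.5 in siNON cells, 40.8% had a dex-enriched peak within 50 kb. Of the interaction genes 41.2% did, so the ratio does not set them apart from induced genes. PDGFA, APOLD1, NSDHL and INSIG1 had no peak of any class within 50 kb.

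Genes lower after depletion in vehicle more often had a peak of any class within 50 kb (866 of 8908 genes, 9.72%, against 6.37%; odds ratio 1.58, 1.41 to 1.78, adjusted p = 1.52e-14 by the same exact test). The ratio was 1.2 (1.11 to 1.31) with the axis score as a covariate. No difference was called for genes that were higher (8.8% against 8.85%, odds ratio 0.994, 0.891 to 1.11, adjusted p = 0.912). CHCHD10 had a dex-enriched peak 7531 bp from its TSS, at chromosome 22, 24117523 to 24117857. In tests added after the data were seen, genes lower after depletion in dexamethasone were more frequent near dex-enriched peaks (1.26, 1.13 to 1.41, adjusted p = 0.000106), a ratio that was 0.99 with the axis score as a covariate, 0.94 for the nearest TSS, 1.13 against matched genes and 1.04 within 1 kb. Genes that were higher were not called there (1.06, adjusted p = 0.346), but were with the axis score (1.44, 1.23 to 1.67), for the nearest TSS (1.37, 1.23 to 1.52) and within 1 kb (1.65, 1.16 to 2.34).

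**Figure D5:**
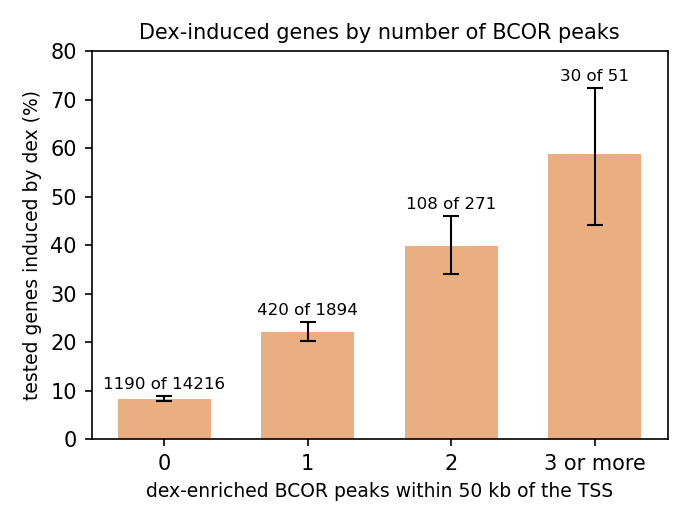
Percent of tested genes that rose with dexamethasone in siNON cells (vertical) by number of dex-enriched BCOR peaks within 50 kb of the TSS (horizontal), with 95% exact binomial intervals. The share goes from 8.37% of genes with 0 peaks to 58.8% of the 51 genes with 3 or more.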

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

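The tests of the shared axis for the interaction and for BCOR, of the axis score and of single terms for genes near peaks, of scaling and of matching on expression were chosen only after the result was seen.

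Among 304 sets of 4 replicates, made of 4 library measures and 72 named genes in 4 groups, 17 (5.59%) held a replicate far from the rest, where chance gives about 5%. The value given is the gap to the nearest replicate as a share of the range. In siNON dex, replicate 4 stood apart in genes detected (0.83; 20004 against 20228 to 20274), ANOS1 (0.868), PCDH19 (0.85), NTS (0.833) and CREBRF (0.936; 10.4 against 5.06 to 5.4 CPM), and replicate 2 in GRIK3 (0.9). In siNON vehicle, replicate 3 stood apart in MYC (0.972; 177.9 against 225.7 to 227.1 CPM), PCGF5 (0.868; 61.0 against 31.3 to 35.2 CPM), PGM2L1 (0.892), CREBRF (0.92) and GLUL (0.968). In siBCOR vehicle, replicate 2 stood apart in NR3C1 (0.888; 1053 against 1121 to 1130 CPM), replicate 1 in PCDH19 (0.925), replicate 3 in INS-IGF2 (0.894) and replicate 4 in TUBA3E, with a value of 1 because it alone had a count. In siBCOR dex, replicate 4 stood apart in ANOS1 (0.903) and replicate 3 in ITGB8 (0.91). The siNON dex replicate 4 and siNON vehicle replicate 3 libraries thus hold 5 values each.

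The response to dexamethasone differed between siNON and siBCOR cells, by the interaction test, in 17 genes: PDGFA (-1.86), S100P (-1.40), APOLD1 (-0.98), ELK1 (-0.72), NSDHL (-0.69), SNX33 (-0.63), ACSL1 (-0.63), SLC39A14 (-0.48), GLUL (-0.47), SHC1 (-0.44), INSIG1 (-0.39), RHOU (0.73), FJX1 (0.77), SNORD137 (-2.15), RTL9 (-1.43), TUBA3FP (-1.43) and SOX18 (1.17). The last 4 were chosen after their values were seen. The cholesterol list was called too (camera adjusted p = 0.0233), but not with an estimated correlation (adjusted p = 0.21) or without siNON dex replicate 4 (0.232).

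The interaction count rose from 17 to 2429 without siNON dex replicate 4. The tables argue against a wrong hormone label, since 33 of 38 glucocorticoid-induced genes in it lay nearer to the other siNON dex libraries than to siNON vehicle. They also argue against transcript length, since 3633 genes were called after each library's trend with length was removed. The siRNA side was not tested. The library's counts differed from siBCOR dex libraries by a chi-square per gene of 19.4 to 28.1, and from its own group by 27.9 to 40.9. Its BCOR level was 70.64 CPM, against 96.76 to 105.9 CPM in its group and 13.77 to 15.46 CPM in siBCOR dex. Variation shared by libraries of all groups is a candidate explanation: without that library the interaction followed the axis loadings of the other 15 with a rho of -0.691 across genes, which are not independent replicates. The axis scores also differ between the groups, so a covariate for them can take away a response to the treatments as well. No biological explanation was tested, and what the axis stands for stays open.

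BCOR mRNA was lower after dexamethasone in siNON cells. The tables argue against scaling as the cause, since the log2 change nearest to 0 under the other scalings was -1.07. They also argue against the shared axis, since the change was -1.15 with the axis score as a covariate. A response of BCOR to the hormone may explain it, as a hypothesis found and tested on the same data, and whether synthesis or decay of the mRNA changed stays open.

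Genes lower after depletion in vehicle lay near BCOR peaks more often than other genes. The tables argue against expression level as the whole cause, with an odds ratio of 1.52 against genes matched on it. In a logistic model of 13430 genes the ratio was 1.56 without other terms, 1.46 with expression and transcript length, 1.14 (1 to 1.29) with axis loading and 1.08 (0.949 to 1.23) with all 3. Variation shared by libraries of all groups may thus account for part of the association. The ratio was 1.2 (1.11 to 1.31) with the axis score as a covariate, but over a different, larger set of called genes and without terms for expression and length. Whether the shared variation is the whole cause therefore stays open. An effect of BCOR at these genes stays open as the biological explanation.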

How the results depend on the processing

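The settings with the axis as a covariate, with siNON dex replicate 4 and siNON vehicle replicate 3 both left out, with the longest transcript, with a 1 kb window and with peaks whose name ends in 2 were chosen only after the results were seen. So were the tests of other splits, except that of the average hormone effect, and the slope through the origin, which replaced the slope with an intercept after its values were seen. The slope with an intercept is counted below among later alternatives.

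Of the values that answer a comparison, 414 under alternatives chosen beforehand and 324 under later ones kept their direction and their side of the threshold or stayed close, and 26 and 16 became weaker, 19 and 14 stronger, 31 and 10 moved and 1 and 1 reversed. Of the values of single genes and of added tests, 5739 and 1483 stayed the same, 338 and 21 became weaker, 1 and 2 stronger and 1 and 2 reversed. No named gene reversed its direction. Under alternatives chosen beforehand, named genes lost their call in 42 of 1356 values for dexamethasone in siNON cells, 22 of 1358 in siBCOR cells, 80 of 1485 for depletion in vehicle and 16 of 1563 in dexamethasone. For the interaction they did in 177 of 299, and PDGFA and ACSL1 in none. Upper-score peak subsets could not be run because every score is 0, and lists were not run with each library left out in turn except for siNON dex replicate 4. Unless a cause is given, the cause was not tested.

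The 17 interaction genes became 4 with relative log expression, 6 with upper-quartile scaling, 6 without a filter, and 8 with a mean of at least 50 counts. They became 68 with DESeq2's Wald test (15 shared) and 3 with a replicate block. Pairing by replicate number was not evident, as 5 of 16 libraries were most like libraries of their own number. Correlations between same-numbered libraries of different groups, after centring by group, ran from -0.772 to 0.75. The main axis of variation weighs on these values, so pairing is not excluded. Leaving out each library gave 2 (without siNON dex replicate 3) to 2429 genes (without siNON dex replicate 4). Leaving out both siNON dex replicate 4 and siNON vehicle replicate 3 gave 1771, the within-group axis 4872 and the axis score 96.

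The within-group axis gave 5977 genes for dexamethasone in siNON cells, 7425 in siBCOR cells and 5955 for depletion in vehicle, by construction more, since it takes up spread within groups. The axis score gave 5057 in siNON cells, 5752 for depletion in vehicle and 3047 in dexamethasone. A fit of only the 2 compared groups gave 1512 genes for depletion in vehicle, with fewer samples behind the spread. Leaving out each library gave 1803 (without siBCOR vehicle replicate 1) to 3463 genes there, and 4168 (without siNON dex replicate 3) to 8167 in dexamethasone. Asking for a log2 change of at least 0.5 as well gave 1625, 1851, 866 and 2479 genes in the order of the comparisons, by construction fewer. The slope of the lower genes was 0.871 over genes called in siNON cells, 1.11 over genes called in siBCOR cells and 0.847 with an intercept, and that of the higher genes 0.936 with an intercept.

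With an estimated correlation camera's adjusted p was, in siNON cells, 0.65 for immediate early and adhesion genes and 0.0754 for Polycomb-type and p53 genes. In siBCOR cells it was 0.13 for Polycomb-type, 0.335 for GR and coregulator, 0.386 for growth control and adhesion, 0.0905 for p53 and 0.172 for cholesterol genes. After depletion in vehicle it was 0.485 for immediate early, 0.24 for neuronal, and 0.392 for G1/S, growth control, stress response, epithelial and ribosomal genes. In dexamethasone it was 0.604 for growth control and ribosomal and 0.473 for stress response genes, and for the interaction 0.21 for cholesterol genes.

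Only those calls by fry that differ from camera's are given here, and fry does not compare a list with other genes. Its adjusted p passed the threshold in siNON cells for NF-kB (0.000539), GR and coregulator (0.0281), neuronal (0.000384) and epithelial genes (0.0281). In siBCOR cells it did for NF-kB (0.0279), stress response (0.0169), neuronal (0.00991), immune cell (0.0247) and epithelial genes (0.00949). After depletion in vehicle it did for NF-kB (0.0108) and PRC1.1 genes (0.000885, BCOR among them) but not immediate early genes (0.0566). In dexamethasone it did for PRC1.1 (0.000861), GR and coregulator (0.0265), G1/S (0.0265), cholesterol (2.28e-05), neuronal (0.000861), epithelial (0.00818) and housekeeping genes (0.0125).

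Without siNON dex replicate 4 camera's adjusted p was 0.115 for immediate early, 0.142 for adhesion and 0.12 for p53 genes in siNON cells, 0.0497 for adhesion genes after depletion in dexamethasone and 0.232 for cholesterol genes in the interaction. With siNON vehicle replicate 3 left out too it was 0.0501 for p53 genes in siNON cells, 0.0251 for adhesion genes after depletion in vehicle, 0.044 for G2/M and 0.046 for adhesion genes in dexamethasone and 0.18 for cholesterol genes in the interaction. With the axis score it was, for growth control genes, 0.032 in siNON cells, 0.0602 in siBCOR cells, 0.0633 for depletion in vehicle and 0.167 in dexamethasone. It was 0.104 for neuronal and epithelial genes in vehicle, and 0.000508 for Polycomb-type, 4.81e-08 for G1/S and 0.0054 for cholesterol genes in dexamethasone. In the interaction it was 0.000736 for immediate early and 0.000307 for Polycomb-type genes. The replicate block changed no call of a list.

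Calls of odds ratios under alternatives, given next, rest on an unadjusted p under 0.05 by Fisher's exact test. The odds ratio of genes that fell with hormone near dex-enriched peaks was 0.871 within 100 kb, 0.844 without both libraries and 0.773 with the axis score, all now called, and reversed to 1.68 for the nearest TSS. That of genes that rose near shared peaks was no longer called within 10 kb (1.07), within 1 kb (1.12), against matched genes (1.14), for a log2 change of at least 0.5 (1.08), with the axis score (1.06) and with peaks whose name ends in 2 (1.1). That of interaction genes was no longer called with the replicate block (3.21), without both libraries (1.1) and within 1 kb (6.19), and reversed to 0 with peaks whose name ends in 2, which lie near only 34 genes. That of genes higher after depletion in vehicle was called without both libraries (0.83) and with peaks whose name ends in 2 (0.869). The added test of genes lower after depletion in dexamethasone reversed for the nearest TSS (0.94), with the axis score (0.99) and with peaks whose name ends in 2 (0.27), and was no longer called against matched genes (1.13) and within 1 kb (1.04). That of genes higher there was called for the nearest TSS (1.37), with the axis score (1.44) and within 1 kb (1.65).

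Other splits of the libraries, the real one counted, tested whether chance gives as many calls. The real split gave the most calls for dexamethasone in siNON cells (1 of 35 splits, 3159 genes against at most 1768) and in siBCOR cells (1 of 35, 3777 against 0). It also did for depletion in dexamethasone (1 of 35, 6437 against 0) and for the average hormone effect (1 of 100, 4562 against 0). The other splits mix libraries of both compared groups, so a real effect widens their spread and lowers their calls. With 35 splits no share can lie below 1 of 35, so these counts alone do not exclude chance. Chance cannot be excluded for depletion in vehicle (2 of 35, 2795 against 4520, the split that exchanges siNON vehicle replicate 3 and siBCOR vehicle replicate 2). That split, which calls more genes than the real one, points to a structure of the samples. For the interaction 6 of 100 splits gave at least the real 17 calls, with up to 5647. They exchanged siNON and siBCOR libraries within a treatment, which can leave the depletion effect of a single treatment in the contrast. The split with 5647 exchanged vehicle libraries only and kept the dex groups. The splits therefore cannot decide on chance for the interaction. In simulated data 44% of 1.5-fold interactions were recovered, so small interactions can be missed. The simulation lacked the axis of variation that the real libraries share, so it does not give the recovery rate in these data.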

Other observations

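The test of the average effects against each other was chosen only after the result was seen.

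Genes were also grouped by the start of their symbol into 44 families of at least 25 protein-coding genes, chosen after the data were seen. In dexamethasone, depletion raised 17 of 35 centrosomal CEP genes and lowered 1, and raised 12 of 29 KLHL genes, adaptors of ubiquitin ligases, and lowered 0. It raised 151 and lowered 48 of 477 zinc finger ZNF genes, against 22 and 38 with the axis score as a covariate, when 5 CEP genes rose and 0 fell. Camera called CEP and ZNF (adjusted p = 0.00107 each) and KLHL (0.0245) at the preset correlation but not with an estimated one (0.591, 0.761 and 0.591). In vehicle, where 1450 of all 16432 genes rose, 7 of 29 TBC genes, 7 of 35 vesicle sorting VPS genes and 6 of 36 kinesin KIF genes rose, and 0, 0 and 2 fell. Camera called them (adjusted p = 0.0246, 0.0298 and 0.0395), but not with an estimated correlation (0.251, 0.203 and 0.396). The medians of these families kept their sign in these comparisons under relative log expression, upper-quartile and DESeq2 scaling.

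Markers of other cells were at mixed levels. Among immune markers, the general one PTPRC reached at most 0.0567 CPM in any group and MS4A1 had 0, while CD68 stood at 13.3, 14, 10.9 and 9.3 CPM in siNON vehicle, siNON dex, siBCOR vehicle and siBCOR dex. Among fibroblast markers COL6A1 stood at 64 and COL1A1 at 34.3 CPM in siNON vehicle, where COL1A2 and FAP had 0, and the neuronal gene UCHL1 stood at 448 CPM. The epithelial genes EPCAM and KRT8, which this kidney line expresses, stood at 275 and 397 CPM in siNON vehicle. With dexamethasone KRT8 rose to 572 CPM and KRT19 fell from 201 to 106 CPM.

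A hypothesis was that depletion moves the hormone response of genes near dex-enriched BCOR peaks apart from that of other genes. Among genes induced on average, the median interaction was -0.0673 for the 657 with such a peak within 50 kb and -0.0566 for the 1514 without, a difference of -0.0106 (jackknife SE 0.0221), so the hypothesis was not borne out.

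A further hypothesis was that more dex-enriched peaks near a gene go with a higher share of induced genes. The share was 8.37% of genes with 0 peaks, 22.2% of 1894 with 1, 39.9% of 271 with 2 and 58.8% of 51 with 3 or more, and the odds ratio of 3 or more against 1 was 5.01 (2.74 to 9.31, p = 2.99e-08 by Fisher's exact test, two-sided). The data are consistent with it, which leaves open whether BCOR at these peaks acts on the genes or accompanies the receptor.

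Another hypothesis was that depletion mimics the hormone, which would make the average effects alike. Across genes, which are not independent replicates, the average hormone effect and the average depletion effect correlated with r = -0.00856 (jackknife SE over libraries 0.0881), against -0.0346 in simulated unchanged groups and -0.0773 with the axis loading removed. This argues against likeness across all genes, and likeness in part of them stays open.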
